A study of Mus musculus with 9 samples.

How the data were processed

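CD11b+ cells were sorted from mouse spleen and profiled on Affymetrix MG-U74Av2 arrays, a 1-color oligonucleotide platform. Per the labels' protocols, RNA was extracted with TRIzol and checked on an Agilent bioanalyzer, and 5 ug per array were turned into biotin-labeled cRNA. The 9 arrays form 3 groups of 3, taken from the sample titles: tumor-free, tumor-bearing without culture, and tumor-bearing after 24 h in complete medium. Nothing in the labels says that replicates came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

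The deposited values are array intensity on a linear scale, 1 MAS5 signal per probe set and array, per the submitters' processing notes; the version and settings of MAS5 are not given in the sources used here. The 2% trimmed mean of every array lay between 100.06 and 100.08, so the arrays had been scaled to a common level before deposit and were used as deposited. No detection calls were used here, so whether a low signal lies above background is unknown, and the number of arrays limits the precision. A signal near the offset has little meaning as a level, and fold changes on the log2(signal + offset) scale understate those of dim genes.

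Signals were transformed to log2(signal + 7.83), the offset being the 20th percentile of all values. Of 12488 probe sets, the 66 control probe sets and the 30% with the lowest mean log2 value were left out, which kept 8695. One linear model with 3 group means was fitted to all 9 arrays in limma 3.58.1 (R 4.3.3), with 6 residual degrees of freedom and an intensity trend in the moderated variance. Each comparison was two-sided, with Benjamini-Hochberg adjustment over all probe sets kept and a threshold of 0.05. Standard errors are those of the moderated fit.

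Gene names came from the platform annotation supplied with the series. It gave 1 symbol for 10855 probe sets and several for 396, and did not list 1237; no gene is named from a probe set with several. Of the single-symbol probe sets, 10839 were matched by gene ID to a RefSeq table of GRCm38.p6, which changed 0 symbols, and no coordinates are printed. A gene is represented by its probe set with the highest mean, which gave 6371 genes. Further tested probe sets were compared only for the largest rises and falls of each comparison, and opposite ones are named beside the gene. Named genes are, per comparison, the 10 largest rises and the 10 largest falls among called probe sets with 1 symbol and non-overlapping groups, up to 4 members with the largest change of each list described, and 31 focus genes. Where 5 or fewer members of a list were called, those outside this rule were also named, chosen after their values were seen: Nfkb2, Irf7, Hmox1, Mrc1, Cxcr2, Gclc, Ifi202b and the pancreas genes outside the rankings.

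The 34 gene lists cover neutrophil granule, mature neutrophil, monocyte, macrophage, activation, chemokine, interferon, MHC class II, NADPH oxidase, cell cycle, immediate early, stress, metabolic, lysosome and ribosomal genes, and markers of other cell types. They were tested with camera with a preset correlation of 0.01, adjusted over the 34 lists of a comparison, with an estimated correlation beside it, and with fry. Some genes stand in several lists, such as Arg1 in the granule and alternative activation lists and C1qa in both macrophage lists. The groups, the tests, the offset, the filter, the lists, the naming rule and most alternatives were chosen before the data were examined. The 5 pancreas lists (digestive enzyme, other acinar, Reg family, islet and duct genes), the spike-in class and the beta-actin ratio as model terms were chosen after.

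The spike-in class splits the arrays at the median of their mean log2 bacterial spike-in signal. It was entered as a block, and the comparisons were repeated within each class; since these fits hold 1 or 2 arrays per group, their counts rest on 2 and 1 residual degrees of freedom, and a lone array is assumed to vary like the others. No scan date or other batch label was used here.

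The model was tested on simulated data made from the real means and spread of the 8695 probe sets, with 200 changed, in 10 simulations. For the first, the second and the third comparison it recovered 15.1%, 16.7% and 14.6% of changes of 1 on the log2 scale, 65.8%, 69.9% and 68.2% of changes of 2, and 96.8%, 95.8% and 97.1% of changes of 4, with 7.6, 6.5 and 5.6 false calls on average. Smaller changes were therefore mostly missed with 3 arrays per group. The simulated noise was drawn independently for each probe set, whereas in the real data whole arrays stood apart from their group. The numbers of false calls therefore need not hold for the real arrays. Overlap between comparisons that share arrays was set beside 50 simulations of unchanged groups, with noise of the same kind.

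Alternatives were quantile normalization, centring on the median, offsets at the 5th percentile (2.11) and 40th percentile (24.7), a floor, no filter or a filter of 50%, variance models without a trend, robust or with array weights, fits of only the 2 groups compared, the replicate number as a block, leaving out each array, a minimum log2 fold change of 1, leaving out less specific probe set types, and averaging a gene's probe sets. The closing section gives their effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.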

Results

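CD11b+ cells, which carry integrin alpha M and in the spleen comprise neutrophils, monocytes, macrophages and some other leukocytes, were sorted from the spleens of female mice aged 8 to 12 weeks. RNA was hybridized to 9 Affymetrix MG-U74Av2 arrays, 3 from tumor-free mice, 3 from tumor-bearing mice without culture (fresh cells) and 3 from tumor-bearing mice after 24 h in complete medium (cultured cells). The tumor is not named in the labels, and the tumor-free cells were not cultured. Arrays are named here by group and replicate number, for example tumor-free 1 or cultured 3. Each array gave a MAS5 signal for 12488 probe sets, of which 8695 entered the tests. The median signal of an array lay between 33.4 and 42.8, and between 16.5% and 23.6% of its values lay below the offset of 7.83 added before log2 was taken.

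In each group 1 array stood apart from a closely similar pair. Across probe sets, tumor-free 2 and 3 correlated at r = 0.957, fresh 1 and 2 at 0.949 and cultured 1 and 2 at 0.929, whereas the lowest r of tumor-free 1 with its group was 0.824, that of fresh 3 was 0.874 and that of cultured 3 was 0.850. Tumor-free 1 correlated more with 5 of the 6 tumor-bearing arrays (0.839 to 0.860) than with either other tumor-free array, and cultured 3 more with tumor-free 2 (0.862), tumor-free 3 (0.854) and fresh 3 (0.861) than with cultured 1. Probe sets are not independent replicates in these correlations. The same arrays differed in their bacterial spike-in controls, which are not RNA of the cells. On arrays scaled to a common level, however, their signal also depends on the overall brightness of the cells' RNA. It need not report the hybridization alone. The mean log2 spike-in signal was 10.36 on tumor-free 1 against 9.77 and 9.65 on its pair, 8.99 on fresh 3 against 9.91 and 9.86, and 9.25 on cultured 3 against at least 10.49 on its pair. Beta-actin, a cytoskeletal gene probed at both ends as a measure of RNA integrity, had a 3'/5' signal ratio of 2.57 on tumor-free 1 against 0.994 and 1.19, of 1.35 on fresh 3 against 1.60 and 1.58, and of 1.16 on cultured 3 against 2.27 and 2.36. The highest values of both measures were on tumor-free 1 and cultured 1 and 2, so they need not be separate lines of evidence. Tumor-free 1, fresh 1 and 2 and cultured 1 and 2 form the high spike-in class and the other 4 arrays the low class. The cut is the median, and the classes abut there, with fresh 2 at 9.86 in the high and tumor-free 2 at 9.77 in the low class. Fresh 1 and 2 lay closer in spike-in signal to tumor-free 2 and 3 than to cultured 1 and 2, so the classes need not be 2 separate runs. The spike-in class, defined from the data, was treated as a possible hybridization batch, and gene list shifts are also given with it as a block and within each class. The first principal component held 30.3% of the variance and the second 24.0%.

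**Figure D1:**
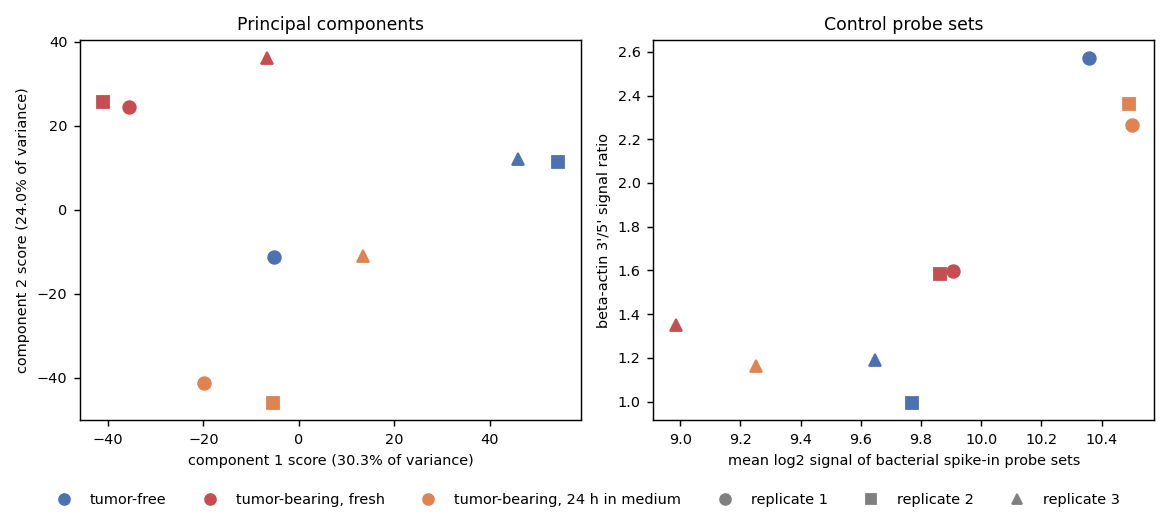
The 9 arrays by their first 2 principal components (30.3% and 24.0% of the variance) and by their control probe sets (mean log2 spike-in signal against the beta-actin 3'/5' ratio), 1 point per array, colored by group with the symbol giving the replicate. In each group 1 array, tumor-free 1, fresh 3 or cultured 3, lies away from the other pair in both plots.

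The first comparison asked how freshly isolated CD11b+ spleen cells of tumor-bearing mice differed from those of tumor-free mice. Genes of the exocrine pancreas rose most. Reg2, a secreted lectin-like protein of the pancreas, went from a mean signal of 4.48 ± 0.702 (SD, n = 3) to 3577 ± 754, a log2 fold change of 8.17 ± 0.56 (SE, adjusted p = 4.14e-05). Reg3b, of the same family, rose by 6.50 ± 0.59, the trypsinogen gene Prss2 by 5.85 ± 0.79, and the chymotrypsinogen gene Ctrb1 by 4.64 ± 0.31. The proinflammatory cytokine gene Il1a rose from 136.5 ± 124.8 to 3347 ± 539 (log2 fold change 4.87 ± 0.63, adjusted p = 0.00274). In the other direction, Klf2, a transcription factor of quiescent leukocytes, fell from 982 ± 475 to 54.5 ± 79.7 (log2 fold change -4.70 ± 0.89, adjusted p = 0.0252), and Usp18, an interferon-induced protease that removes ISG15 from proteins, fell from 124 ± 52.9 to 3.79 ± 1.75 (-3.45 ± 0.60, adjusted p = 0.0162).

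Of the 10 genes with the largest rises, 9 were pancreatic or epithelial secretory genes and the other was Il1a. Besides those named, these were Reg3a (log2 fold change 5.74), Pnliprp1 (5.54), encoding a pancreatic lipase-related protein, Dmbt1 (5.02), encoding a scavenger-receptor protein of epithelial secretions, Reg1 (4.60) and the zymogen granule gene Zg16 (4.47). The 5 lists of pancreas genes were written after these values had been seen, so their counts are not independent evidence. The lists held 23 digestive enzyme, 15 other acinar, 7 Reg family, 14 islet and 10 duct genes, not all of them measured. A measured gene had a probe set that passed the filter on the mean over all 9 arrays. A gene dim in the other groups could pass it only through the fresh arrays, so the counts do not describe whole families. Of 10 measured digestive enzyme genes 7 rose, and 8 rose when adjusted over the list alone. The median log2 fold change was 3.01 (camera adjusted p = 6.31e-15, adjusted p = 0.0301 with an estimated correlation). All 5 measured Reg family genes rose (median 5.74, adjusted p = 3.16e-15, adjusted p = 0.0152 with an estimated correlation). Of 6 other acinar genes 3 rose, the kallikrein gene Klk1 (3.81), Zg16 and the zymogen granule gene Sycn (2.56), with a list median of 1.55 (adjusted p = 0.000452, adjusted p = 0.14 with an estimated correlation). Neither of the 2 islet genes nor any of the 3 duct genes passed limma's test (0 and 1 at an unadjusted p below 0.05), although 1 duct gene, Muc1 (1.31), rose when adjusted over the list alone. Camera's adjusted p was 0.787 for the islet list and 0.0699 for the duct list. Cela1 (0.86), Pnliprp2 (1.32) and Pla2g1b (0.38), also digestive enzyme genes, did not pass it either. Sycn lost its call without tumor-free 2, tumor-free 3, fresh 1 or fresh 2 (adjusted p up to 0.138).

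Genes of complement and other macrophage products were among the largest falls. The complement component genes C1qa and C1qb, made by macrophages, changed by -2.99 ± 0.62 and -2.91 ± 0.53, C1qa from a signal of 1608 ± 1083 to 149 ± 22.2 (n = 3 each). Aif1, a calcium-binding protein of macrophages, changed by -2.96 ± 0.57, and Rgs2, a regulator of G protein signaling, by -3.30 ± 0.48. The tetraspanin gene Tspan4 (-3.02 ± 0.33), the sodium, potassium and chloride cotransporter gene Slc12a2 (-3.01 ± 0.46), Otulinl (-2.77 ± 0.56) and Sash1 (-2.75 ± 0.57) completed the 10. The calls of all 10 named rises held when any 1 array was left out, with a highest adjusted p of 0.0282, and 9 of them, all except Il1a (adjusted p = 0.0788), when the closest 2 arrays of each group were averaged. Among the named falls only Rgs2, Tspan4 and Slc12a2 kept the call whichever array was left out, and only Tspan4 with the averaged arrays (adjusted p up to 0.455). Klf2, Usp18, C1qa, Aif1, C1qb, Otulinl and Sash1 each lost it without 1 or more of tumor-free 2 and 3, fresh 1, 2 and 3 and cultured 1 and 2, with adjusted p up to 0.17. A further C1qb probe set gave 0.48, opposite to the chosen one, and a further Reg2 probe set 0.68. Neither passed the test.

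**Figure D2:**
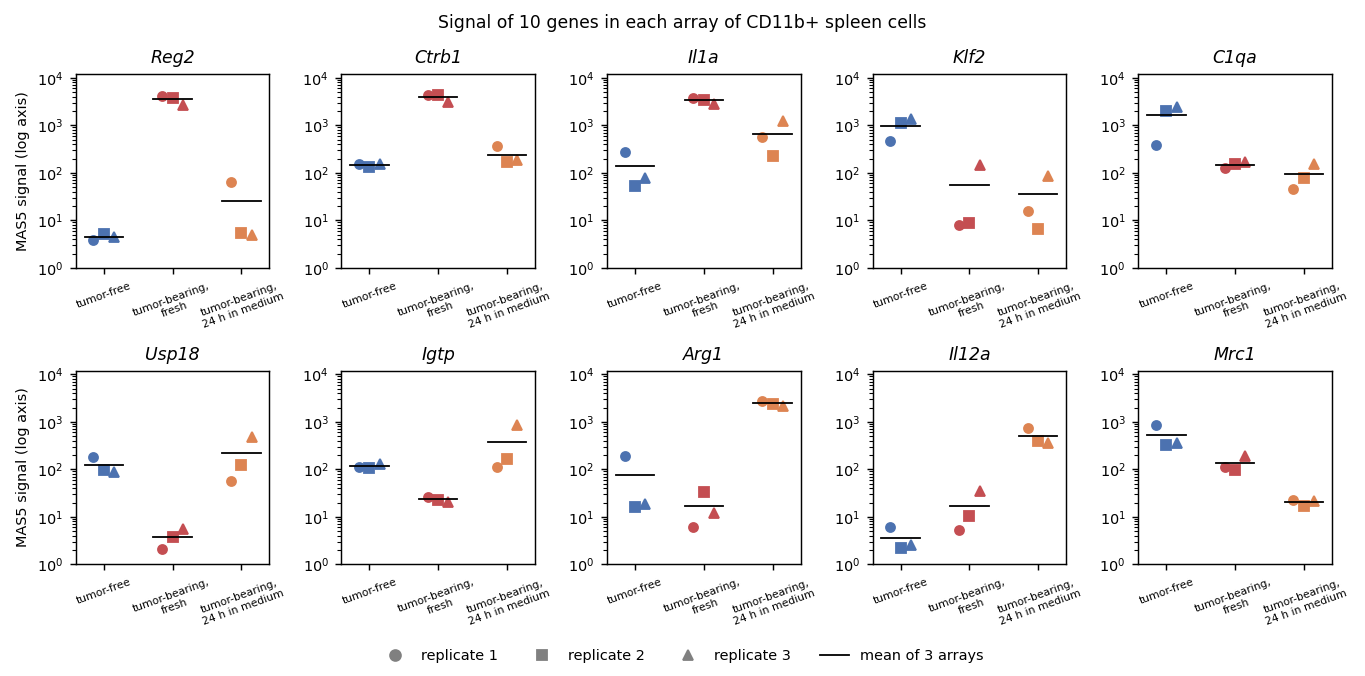
MAS5 signal (log axis) of 10 genes on each of the 9 arrays, by group, with the symbol giving the replicate and the bar the mean of 3 arrays. Reg2, Ctrb1 and Il1a are highest in fresh tumor-bearing cells, Usp18 and Igtp lowest there, Arg1 and Il12a highest after 24 h in medium, and Klf2, C1qa and Mrc1 highest in tumor-free cells.

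Lists of stimulus-responsive genes shifted in opposite ways in the fresh cells. Of 19 measured genes of the immediate early list, mostly transcription factors and regulators induced within minutes of stimulation, 7 fell. Among these were Egr1 (-2.69, limma adjusted p = 0.00697), Zfp36 (-2.50, adjusted p = 0.0252) and Klf2. The list holds Klf2 although it is a factor of quiescent leukocytes. 12 fell and 1 rose when adjusted over the list alone. The list median was -1.20 (camera adjusted p = 7.73e-06, adjusted p = 0.332 with an estimated correlation), -1.17 with the spike-in class as a block, and -1.41 and -0.76 within the high and low class. Of 25 genes of classical activation and NF-kB, the transcription factor of inflammatory induction, 2 rose, Il1a and Nfkb2 (1.55, adjusted p = 0.0261), while 8 rose and 1 fell when adjusted over the list alone. The cytokine gene Il6 (3.22, adjusted p = 0.0861) and the signaling adaptor gene Traf1 (3.15, adjusted p = 0.0542) missed the threshold. The median of this list was 0.94 (adjusted p = 1.75e-05, adjusted p = 0.268 with an estimated correlation), 1.16 with the block, and 0.39 and 1.54 within the high and low class. Zfp36 and Klf2 lost their calls without tumor-free 2, tumor-free 3, fresh 1 or fresh 2 (adjusted p up to 0.122 and 0.12), and Nfkb2 without tumor-free 2, tumor-free 3 or fresh 1 (up to 0.126).

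Lists of interferon-induced genes, which encode antiviral and GTP-binding effectors, shifted downward in the fresh cells. Of 17 type I interferon response genes 2 fell, Usp18 and the transcription factor gene Irf7 (-1.95, adjusted p = 0.0304), and 7 fell when adjusted over the list alone. Ifit3 (-3.06, adjusted p = 0.172), Ifit2 (-2.77) and Ifit1 (-2.39) did not pass the test. The list median was -1.73 (adjusted p = 1.76e-06, adjusted p = 0.438 with an estimated correlation), -1.53 with the block, and -1.92 and -0.77 within the high and low class. None of 21 interferon gamma response genes passed limma's test over all probe sets, 5 had an unadjusted p below 0.05, and 4 fell when adjusted over the list alone. Ifi47, a GTPase gene, was at -3.03 (adjusted p = 0.066) and Irgm1, another, at -2.39. Their list median was -0.57 (adjusted p = 0.00248, adjusted p = 0.535 with an estimated correlation), -0.48 with the block, and -0.46 and -0.81 within the classes, and it was -0.87 without tumor-free 1. Usp18 lost its call without tumor-free 2, fresh 1 or fresh 2 (adjusted p up to 0.0769), and Irf7 without tumor-free 2, tumor-free 3 or fresh 1, 2 or 3 (up to 0.147).

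Lists of myeloid subsets also shifted. Of 13 secondary and tertiary granule genes of neutrophils none passed limma's test (3 at an unadjusted p below 0.05), and 3 rose when adjusted over the list alone. The median was 1.09 (adjusted p = 0.00172, adjusted p = 0.282 with an estimated correlation), 1.58 with the block and 1.35 and 0.59 within the high and low class, with the collagenase gene Mmp8 at 2.52 and the chitinase-like gene Chil3 at 2.31. Of 10 primary granule genes none passed (4 unadjusted) and 3 rose when adjusted over the list alone, with the myeloperoxidase gene Mpo at 3.03 (adjusted p = 0.0953) and the cathepsin G gene Ctsg at 2.58. Their median was 0.59 (adjusted p = 0.00997, adjusted p = 0.428 with an estimated correlation), 0.91 with the block and 0.95 and 1.26 within the classes. Of 19 macrophage genes 3 fell, C1qa, C1qb and the mannose receptor gene Mrc1, and 6 fell when adjusted over the list alone (median -0.73, adjusted p = 0.00248, adjusted p = 0.268 with an estimated correlation). It was -0.67 with the block, and -0.78 and -1.25 within the classes. Of 10 red pulp macrophage genes 3 fell, C1qa, C1qb and the heme oxygenase gene Hmox1 (-1.77), and 5 when adjusted over the list alone. Their median was -2.15 (adjusted p = 6.69e-05, adjusted p = 0.457 with an estimated correlation) and -1.75 with the block, but 0.10 within the high class and -2.68 within the low class, so the direction did not hold within both. Of 11 patrolling monocyte genes 1 fell, Klf2, and 3 when adjusted over the list alone (median -0.65, adjusted p = 0.00922, adjusted p = 0.438 with an estimated correlation). It was -0.74 with the block, and -0.17 and -1.52 within the classes. Without tumor-free 1 the secondary and tertiary granule median was 0.69 and the patrolling monocyte median -1.62, the macrophage median was -0.47 without tumor-free 2, and the red pulp macrophage median was -1.12 and -0.99 without tumor-free 2 and 3. The primary granule list lost its call without fresh 3 (adjusted p = 0.276) and the patrolling monocyte list without tumor-free 2 (adjusted p = 0.0574). C1qa, C1qb, Hmox1, Mrc1 and Klf2 each lost their calls without tumor-free 2, tumor-free 3, fresh 1 or fresh 2, and some of them without fresh 3, cultured 1 or cultured 2 (adjusted p up to 0.165, 0.104, 0.139, 0.181 and 0.12).

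Lists of other cell types that a spleen sort can hold, and of chaperones, shifted as well. Of 22 erythroid genes none passed limma's test (6 at an unadjusted p below 0.05) and 3 rose when adjusted over the list alone. The alpha globin gene Hba-a1 was at 2.18 and the heme synthesis gene Alas2 at 2.15 (adjusted p = 0.0933). The erythroid median was 0.50 (adjusted p = 0.00408, adjusted p = 0.268 with an estimated correlation), 0.51 with the block and 0.80 and 0.61 within the high and low class, and the call was lost without tumor-free 1 (adjusted p = 0.0816). Of 8 plasma cell genes none passed (2 unadjusted) and 2 rose when adjusted over the list alone, with a median of 0.71 (adjusted p = 0.0168, adjusted p = 0.268 with an estimated correlation), 0.97 with the block and 1.41 and 0.80 within the classes. The call was lost without fresh 3 (adjusted p = 0.204). None of 13 heat shock protein genes, which encode chaperones, passed (4 unadjusted), nor did any when adjusted over the list alone. Their median was -0.61 (adjusted p = 0.00823, adjusted p = 0.535 with an estimated correlation), -0.60 with the block and -1.11 and -0.39 within the classes, with Hspa1b at -2.56, and the call was lost without tumor-free 1 (median -0.26, adjusted p = 0.316). With the spike-in class as a block the NADPH oxidase, cell cycle and cytosolic ribosomal protein lists passed too, with medians of 0.90, 0.28 and -0.37 (adjusted p = 0.0222, 0.00865 and 0.0246). With an estimated correlation and no block, camera's adjusted p for these lists was 0.79, 0.79 and 0.86.

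In all, 165 of 8695 probe sets passed limma's test at an adjusted p below 0.05, 82 higher and 83 lower in fresh tumor-bearing cells, and 1449 had an unadjusted p below 0.05. All 124 genes whose representative probe set was called had non-overlapping groups, as did 22.4% of all probe sets tested, against 10% by chance. A call with 3 arrays per group makes such separation likely, so it is no further evidence. The count was 623 without tumor-free 1 (271 higher and 352 lower), 66 without tumor-free 2 (45 and 21), 67 without tumor-free 3 (45 and 22), 63 without fresh 1 (37 and 26) and 65 without fresh 2 (44 and 21). Without 69 pancreas-related probe sets 38 were higher and 83 lower. These 69 belong to the pancreas lists or follow their mean across these arrays (r above 0.9), whatever the gene. That only higher calls were lost follows from this choice and does not measure the share of pancreas genes. With the closest 2 arrays of each group averaged, a setting chosen after the data were seen, it was 23 (21 higher and only 2 lower), and the single genes named here that kept their calls were pancreatic or epithelial secretory genes and Tspan4. It was 3174 with array weights (1562 and 1612), 402 with the beta-actin ratio as a covariate (177 and 225) and 277 with the spike-in class as a block, and within the high and low class, with 2 and 1 residual degrees of freedom, 411 and 1967.

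The second comparison asked what 24 h in complete medium did to the cells of tumor-bearing mice. Arg1, which encodes the arginine-degrading enzyme arginase 1, rose from a signal of 17.2 ± 14.4 (SD, n = 3) to 2438 ± 297, a log2 fold change of 6.76 ± 0.70 (adjusted p = 0.000857). Il12a, the p35 subunit of interleukin-12, rose from 16.9 ± 15.9 to 502 ± 213.5 (4.47 ± 0.45, adjusted p = 0.000759). The macrophage elastase gene Mmp12 went from 753 ± 413 to 5619 ± 2629 (2.92 ± 0.54, adjusted p = 0.0176) and Usp18 from 3.79 ± 1.75 to 217 ± 224 (3.78 ± 0.60, adjusted p = 0.00866). The 10 largest falls were all pancreatic or epithelial secretory genes, led by Reg2 at -7.25 ± 0.56, from 3577 ± 754 to 25.3 ± 34.9 (adjusted p = 0.000141).

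The other named rises were the interferon-induced GTPase genes Ifi47 (log2 fold change 3.75, adjusted p = 0.0206) and Igtp (3.08, adjusted p = 0.0181), the costimulatory receptor gene Tnfrsf9 (3.66, adjusted p = 0.0158), AW112010 (2.86), the protein C receptor gene Procr (2.81) and the cytidine deaminase gene Apobec1 (2.79). After Reg2, the falls were Reg3b (-5.97), Prss2 (-5.89), Pnliprp1 (-5.13), Reg3a (-4.79), Zg16 (-4.62), Dmbt1 (-4.37), Reg1 (-4.13), Reg3g (-4.05) and Ctrb1 (-4.05). In the pancreas lists, 6 of 10 measured digestive enzyme genes fell (median -2.21, camera adjusted p = 1.21e-14, adjusted p = 0.0315 with an estimated correlation). All 5 measured Reg family genes fell too (-4.79, camera adjusted p = 3.84e-15, adjusted p = 0.0154 with an estimated correlation). Of 6 other acinar genes 3 fell (-1.32, adjusted p = 4.36e-05, adjusted p = 0.0901 with an estimated correlation), and of 3 duct genes the mucin gene Muc1 did (-1.58), with a list adjusted p of 0.0545. The islet list gave 0.703. Muc1 lost its call in 7 of the 9 fits that leave out 1 array, all except those without tumor-free 1 or fresh 2 (adjusted p up to 0.167). The calls of all 10 named falls held whichever array was left out (highest adjusted p = 0.0268), as did those of Arg1, Il12a and Usp18. With the closest 2 arrays of each group averaged these calls held too, except that of Usp18 (adjusted p = 0.0902), and the other 7 named rises were lost (up to 0.273). Ifi47, Tnfrsf9, Igtp, Mmp12, AW112010, Procr and Apobec1 each lost the call without 1 or more of fresh 1, 2 and 3 and cultured 1 and 2, with adjusted p up to 0.103. A further Reg2 probe set gave 0.14, opposite to the chosen one, and a further Tnfrsf9 probe set 0.16.

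Lists of interferon-induced genes shifted upward in culture. Of 21 interferon gamma response genes 6 rose, among them Ifi47, Igtp and Irgm1 (2.68, adjusted p = 0.047), and 12 rose when adjusted over the list alone, while Gbp2, a guanylate-binding protein gene, was at 3.79 (adjusted p = 0.0513). The list median was 1.08 (camera adjusted p = 2.14e-07, adjusted p = 0.524 with an estimated correlation), the same with the block, and 0.86 and 2.32 within the high and low class, and it was 1.70 without cultured 1 and 0.69 without cultured 3. Of 17 type I interferon response genes 3 rose, Usp18, Irf7 (2.57, adjusted p = 0.00706) and Ifi202b (2.32, adjusted p = 0.0115), and 11 rose when adjusted over the list alone. Ifit2 (2.82) and Ifit3 (2.59) did not pass the test. Their median was 1.39 (adjusted p = 5.07e-07, adjusted p = 0.524 with an estimated correlation), and 0.96 and 2.65 within the classes, and it was 0.93 without cultured 3, the array with the highest signals of this list. Of the 9 lists called in this comparison, every median was the same with the block, since both groups hold 2 arrays of the high class and 1 of the low class. Usp18 and Irf7 kept their calls whichever array was left out but not with the closest 2 arrays of each group averaged, whereas Ifi202b lost its call without fresh 1 or 2 (adjusted p up to 0.0605) and Igtp without fresh 1, 2 or 3 (up to 0.0781). Ifi47 lost its call without fresh 1, 2 or 3 or cultured 2 (up to 0.0974), and Irgm1 without any of these, tumor-free 2, tumor-free 3 or cultured 3 (up to 0.159).

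Lists of primary granule, cell cycle, immediate early and erythroid genes shifted downward in culture. Of 10 primary granule genes 2 fell, Mpo (-3.68, adjusted p = 0.0409) and the proteinase 3 gene Prtn3 (-2.56, adjusted p = 0.0355), and 5 fell when adjusted over the list alone (median -1.21, camera adjusted p = 0.00172, adjusted p = 0.524 with an estimated correlation). Within the high and low class it was -1.25 and -1.93. That call was lost without fresh 3 (adjusted p = 0.0959). The secondary and tertiary granule list did not pass (median -1.37, mean -0.39, adjusted p = 0.293), and of its 13 members 1 rose, Arg1 (2 rose and 1 fell when adjusted over the list alone). Of 33 cell cycle genes 2 fell, the microtubule regulator gene Stmn1 (-2.83, adjusted p = 0.0434) and the replicative helicase gene Mcm4 (-1.49, adjusted p = 0.0261), and 4 when adjusted over the list alone (median -0.57, adjusted p = 5.86e-05, adjusted p = 0.531 with an estimated correlation). Within the classes it was -0.66 and -0.09, and without cultured 2 it was -0.32. Of 19 immediate early genes 2 fell, Fosb (-1.58) and the phosphatase gene Dusp1 (-1.46), and 7 when adjusted over the list alone (median -0.61, adjusted p = 0.000179, adjusted p = 0.524 with an estimated correlation). Within the classes it was -0.30 and -1.37. None of 22 erythroid genes passed limma's test (8 at an unadjusted p below 0.05) and 2 fell when adjusted over the list alone, with the blood group gene Rhd at -1.85 (median -0.67, adjusted p = 0.000941, adjusted p = 0.524 with an estimated correlation). Within the classes it was -0.58 and -0.12. Mpo, Prtn3, Stmn1, Mcm4, Fosb and Dusp1 each lost the call without fresh 1, 2 or 3 or cultured 2, and some of them without tumor-free 2, tumor-free 3 or cultured 1 (adjusted p up to 0.165, 0.134, 0.17, 0.115, 0.119 and 0.117).

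Metabolic and lysosome lists shifted upward in culture with few single calls. None of 21 hypoxia and glycolysis genes passed limma's test (10 at an unadjusted p below 0.05) and 3 rose when adjusted over the list alone, with the glycolytic genes Aldoc at 1.82, Pgk1 at 1.68 and Aldoa at 1.60 (adjusted p = 0.0502). The median was 0.78 (adjusted p = 0.000179, adjusted p = 0.531 with an estimated correlation), and 0.89 and 0.59 within the high and low class. Of 28 lysosome genes 1 rose, Npc2 (1.98, adjusted p = 0.00954), a cholesterol-binding protein of lysosomes, and 2 when adjusted over the list alone (median 0.39, adjusted p = 0.0167, adjusted p = 0.524 with an estimated correlation). Within the classes it was 0.50 and 0.44. The call of Npc2 was lost without cultured 2 (adjusted p = 0.0544). None of 12 cholesterol biosynthesis genes passed (2 unadjusted), nor did any when adjusted over the list alone, with the squalene synthase gene Fdft1 at 1.37. Their median was 0.43 (adjusted p = 0.0359, adjusted p = 0.524 with an estimated correlation), and 0.48 and 0.35 within the classes. The call was lost without fresh 1, fresh 3, cultured 1 or cultured 3 (adjusted p up to 0.116). The classical activation and NF-kB list did not pass (median -0.84, adjusted p = 0.0782), with 1 of 25 members up, Il12a (4 up and 5 down when adjusted over the list alone). It passed, downward, in 11 of 25 alternative settings, among them without tumor-free 1, tumor-free 3, fresh 1, fresh 2 or cultured 2 (adjusted p from 0.00846 to 0.635 over all). The oxidative stress list did not pass (median 0.50, adjusted p = 0.127), although 3 of its 20 members rose and 1 fell (5 and 2 when adjusted over the list alone). The glutathione synthesis gene Gclm was at 2.28 (adjusted p = 0.0158), Gclc of the same pathway at 1.61 (adjusted p = 0.0434), Hmox1 at 1.71 (adjusted p = 0.0232) and the metallothionein gene Mt1 at -2.92 (adjusted p = 0.0356). These 4 calls were each lost without fresh 1, fresh 2 or cultured 2, and some without fresh 3, cultured 1, tumor-free 2 or tumor-free 3 (adjusted p up to 0.0781, 0.183, 0.115 and 0.15).

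After culture 234 probe sets passed limma's test, 132 higher and 102 lower, and 1420 had an unadjusted p below 0.05. All 160 genes whose representative probe set was called had non-overlapping groups, as did 22.2% of all probe sets tested, against 10% by chance. The count was 489 without tumor-free 1 (281 higher and 208 lower), 74 without fresh 1 (31 and 43), 81 without fresh 2 (31 and 50), 142 without cultured 1 (72 and 70), 86 without cultured 2 (30 and 56) and 432 without cultured 3 (243 and 189). Without the pancreas-related probe sets 132 were higher and 62 lower. That only lower calls were lost follows from choosing these probe sets in part by their pattern across the same arrays. With the closest 2 arrays of each group averaged it was 21, only 4 higher and 17 lower, and the single genes named here that kept their calls were pancreatic or epithelial secretory genes, Arg1 and Il12a. It was 1902 with array weights (1102 and 800), 441 with the beta-actin covariate (269 and 172) and 556 with the spike-in class as a block, and within the high and low class, with 2 and 1 residual degrees of freedom, 1049 and 1393.

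Most genes called in both comparisons moved in opposite directions. Among 8695 probe sets, 47 rose in fresh tumor-bearing cells and fell in culture, pancreatic genes such as Reg2 and Ctrb1 among them, 22 fell and then rose, Usp18 among them, 2 fell in both, Mrc1 and Fosb, and 0 rose in both by limma's test (10 at an unadjusted p below 0.05 in each). Independent lists of these sizes would share 0.962, 1.26, 0.974 and 1.24 probe sets in these 4 combinations. The comparisons share the fresh arrays with opposite sign, so that chance alone favors opposite calls. In 50 simulations of unchanged groups the number of opposite calls was 0 each time, but the first comparison then had only 0.08 calls on average, so this says nothing about the overlap of called genes. The correlation of the log2 fold changes was -0.59 against -0.503 simulated, and the covariance -0.313 against -0.101. How much of the overlap comes from the shared arrays, which are too few to be divided, is not known. The opposite calls numbered 69 in all, and 188 without tumor-free 1, 41 without tumor-free 2, 41 without tumor-free 3, 30 without fresh 1, 34 without fresh 2, 43 without cultured 2, 135 with the spike-in class as a block, 145 with the beta-actin covariate and 980 with array weights. With the closest 2 arrays averaged there were 16, all of them up then down. Only 1 of the 69 also differed between cultured and tumor-free cells. When 69 probe sets that belong to the pancreas lists or follow them across arrays were left out, 31 opposite calls remained, 9 up then down and 22 down then up, and the counts of the first and second comparison were 121 and 194. To follow these lists is to rise and then fall, so a loss of up then down calls alone was set by the choice.

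The third comparison set cultured cells of tumor-bearing mice against uncultured cells of tumor-free mice, so that tumor and culture act together. Arg1 rose from 74.4 ± 98.6 (SD, n = 3) in tumor-free cells to 2438 ± 297 in cultured cells (log2 fold change 5.60 ± 0.70, adjusted p = 0.00519). Il12a rose from 3.61 ± 2.13 to 502 ± 213.5 (5.42 ± 0.45, adjusted p = 0.00112), from a level below the offset, so that the order of Arg1 and Il12a depends on the offset and turns with the offset at the 5th percentile. The apolipoprotein gene Apoe fell from 2733 ± 984 to 132 ± 139 (-4.98 ± 0.81, adjusted p = 0.016), and Mrc1 from 516 ± 299.5 to 20.2 ± 3.08 (-4.09 ± 0.39, adjusted p = 0.00142). Mrc1 was intermediate in fresh cells, at 134.5 ± 53.0. None of the 5 pancreas lists passed camera's test, the lowest adjusted p being 0.421.

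The further named rises were Tnfrsf9 (log2 fold change 3.65), the oxidoreductase gene Ptgr1 (3.17), the glutathione conjugate exporter gene Abcc1 (2.89), the coagulation factor gene F10 (2.88), the prostaglandin E synthase gene Ptges (2.82), the paraoxonase gene Pon3 (2.82), Mmp12 (2.79) and the mitochondrial superoxide dismutase gene Sod2 (2.71). The further falls were Klf2 (-4.83), C1qa (-3.78), Slc12a2 (-3.66), C1qb (-3.64), Fosb (-3.45), C1qc (-3.29), the metalloproteinase gene Adamdec1 (-3.19) and Egr1 (-3.13). With the closest 2 arrays of each group averaged, 0 of these 20 named genes kept the call by limma (adjusted p from 0.0586 to 0.573). Each group then held 2 samples, and 475 probe sets had an unadjusted p below 0.05. All 20 kept their direction, with Arg1 at 5.07, Mrc1 at -4.29 and C1qc at -2.68. In a fit of only the 2 groups compared 5 kept the call, Arg1, Il12a, Mrc1, Fosb and Adamdec1. These 5, Ptgr1, Abcc1, Pon3, Slc12a2 and Egr1 kept it whichever array was left out. Tnfrsf9, F10, Ptges, Mmp12 and Sod2 lost it without 1 or more of tumor-free 2 and 3, fresh 1, 2 and 3 and cultured 1 and 2, with adjusted p up to 0.165, and Apoe, Klf2, C1qa, C1qb and C1qc likewise lost it in 1 or more such fits, with adjusted p up to 0.154. Further probe sets of Egr1 (0.58) and C1qb (0.18) lay opposite to the chosen ones and did not pass the test, nor did a further Tnfrsf9 probe set (0.05, adjusted p = 0.981).

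Immediate early genes had the lowest camera p of this comparison, while the medians of the red pulp macrophage and patrolling monocyte lists were further from 0. Of 19 members 9 fell, among them Klf2, Fosb, Egr1 and Zfp36 (-2.82, adjusted p = 0.0182), and 16 fell when adjusted over the list alone. The median was -1.52 (camera adjusted p = 7.05e-17, adjusted p = 0.135 with an estimated correlation), -1.80 with the spike-in block, and -1.71 and -2.43 within the high and low class. Of 11 patrolling monocyte genes 2 fell, Apoe and Klf2, and 7 when adjusted over the list alone (median -1.73, adjusted p = 1.32e-06, adjusted p = 0.204 with an estimated correlation). It was -1.33 with the block, and -0.64 and -1.46 within the classes. Of 10 red pulp macrophage genes 3 fell, C1qa, C1qb and C1qc, and 4 when adjusted over the list alone. Their median was -2.21 (adjusted p = 2.8e-05, adjusted p = 0.409 with an estimated correlation) and -1.71 with the block, but 0.57 within the high class and -3.52 within the low class, so the direction did not hold within both, and it was -0.91 and -0.74 without tumor-free 2 and 3. None of 13 heat shock protein genes passed limma's test (6 at an unadjusted p below 0.05), nor did any when adjusted over the list alone. Their median was -0.65 (adjusted p = 0.000928, adjusted p = 0.409 with an estimated correlation), -0.81 with the block and -1.53 and 0.00 within the classes, the median was -1.15 without cultured 3, and the call was lost without tumor-free 1 (adjusted p = 0.233). Zfp36 lost its call without tumor-free 2, tumor-free 3 or cultured 2 (up to 0.0782), Klf2 and C1qa without those or cultured 1 (up to 0.127 and 0.0801), Apoe without tumor-free 2, tumor-free 3 or cultured 1 (up to 0.0801), C1qb without tumor-free 2 or 3 (up to 0.0612), and C1qc in 7 such fits, all except those without tumor-free 1 or cultured 3 (up to 0.154).

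Of 19 macrophage genes 5 fell, Apoe, Mrc1, C1qa, C1qb and C1qc, and 1 rose, Mmp12 (6 and 4 when adjusted over the list alone), and the list did not pass (median -0.03, adjusted p = 0.242). Hypoxia, glycolysis and oxidative stress lists shifted upward in cultured cells. None of 21 hypoxia and glycolysis genes passed limma's test over all probe sets, but 16 had an unadjusted p below 0.05 and 15 rose when adjusted over the list alone, with the growth factor gene Vegfa at 2.76 (adjusted p = 0.0898) and Pgk1 at 2.09. Their median was 1.28 (adjusted p = 1.53e-09, adjusted p = 0.329 with an estimated correlation), 1.06 with the block and 0.61 and 1.37 within the high and low class. Of 20 oxidative stress genes 3 rose, Sod2, Gclm (2.13, adjusted p = 0.0346) and the thioredoxin reductase gene Txnrd1 (1.95, adjusted p = 0.0314), and 6 when adjusted over the list alone (median 0.43, adjusted p = 0.00032, adjusted p = 0.135 with an estimated correlation). It was 0.34 with the block, and 0.81 and 0.60 within the classes. None of 28 lysosome genes passed (5 unadjusted) and 2 rose when adjusted over the list alone, with the cathepsin gene Ctsl at 3.33 (adjusted p = 0.0598). The lysosome median was 0.37 (adjusted p = 0.0387, adjusted p = 0.331 with an estimated correlation), 0.32 with the block and 0.18 and 0.22 within the classes. The call was lost without tumor-free 3 (median 0.23), fresh 3 or cultured 2 (adjusted p up to 0.129). None of 12 cholesterol biosynthesis genes passed (1 unadjusted) and 1 rose when adjusted over the list alone, with a median of 0.35 (adjusted p = 0.0355, adjusted p = 0.406 with an estimated correlation) and 0.08 and 0.44 within the classes. That call was lost with the block (median 0.21, adjusted p = 0.0662) and without tumor-free 2, tumor-free 3 (median 0.21), cultured 1 or cultured 3 (up to 0.105), and the median was 0.60 without tumor-free 1 and 0.54 without cultured 2. Sod2, Gclm and Txnrd1 each lost their calls without tumor-free 2, tumor-free 3 or cultured 2, and some without cultured 1 or a fresh array (up to 0.112, 0.13 and 0.152).

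Lists of classical activation, interferon gamma and secondary and tertiary granule genes also shifted upward against tumor-free cells. Of 21 interferon gamma response genes 3 rose, all of them antigen-processing or regulatory genes, namely Tap1 (1.66, adjusted p = 0.0299), Tapbp (1.63, adjusted p = 0.0147) and Irf1 (1.33, adjusted p = 0.0362), and 3 when adjusted over the list alone. The median was 0.50 (adjusted p = 0.00651, adjusted p = 0.625 with an estimated correlation), 0.75 with the block and 0.29 and 1.33 within the high and low class. The median was 0.82 without cultured 1 and turned to -0.09 without cultured 3, and the call was lost without tumor-free 1 or cultured 3 (adjusted p up to 0.433). Of 25 classical activation and NF-kB genes 1 rose, Il12a, and 4 when adjusted over the list alone, with the chemokine gene Ccl5 at 4.69 (adjusted p = 0.0502). The median was 0.43 (adjusted p = 0.0169, adjusted p = 0.406 with an estimated correlation) and 0.53 with the block, but -0.19 within the high class and 0.60 within the low class, and the call was lost without tumor-free 3 or cultured 3 (adjusted p up to 0.122). Of 13 secondary and tertiary granule genes 2 rose, Arg1, which the list holds as a granule protein, and the NADPH oxidase gene Cybb (2.41), and 4 when adjusted over the list alone. The median was 0.27 (adjusted p = 0.0355, adjusted p = 0.406 with an estimated correlation), 0.81 with the block and 0.75 and 1.04 within the classes. It was 0.45 and 0.75 without tumor-free 2 and 3 and 0.95 without cultured 2, but turned to -0.15 without tumor-free 1 and -0.28 without cultured 3. The call was lost without tumor-free 1, fresh 3 or cultured 3 (adjusted p up to 0.546). The primary granule list did not pass (median -0.42, adjusted p = 0.535). Tap1, Tapbp and Irf1 each lost their calls without tumor-free 2, tumor-free 3 or cultured 2, and Tap1 and Irf1 also without fresh 1, fresh 2 or, for Irf1, cultured 1 (up to 0.124, 0.0873 and 0.165). Cybb lost its call without tumor-free 3, cultured 1 or cultured 2 (up to 0.086). The type I interferon list did not pass (median 0.09, adjusted p = 0.726).

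A further 4 lists shifted downward with few or no single calls. None of 33 cell cycle genes passed limma's test (6 at an unadjusted p below 0.05), nor did any when adjusted over the list alone. The median was -0.36 (adjusted p = 0.00815, adjusted p = 0.625 with an estimated correlation), -0.30 with the block and -0.61 and 0.18 within the high and low class, -0.60 without cultured 3, and the call was lost without tumor-free 1 or cultured 2 (median -0.20 in the latter, adjusted p up to 0.393). None of 13 MHC class II genes, which present antigen, passed (2 unadjusted), nor did any when adjusted over the list alone. Their median was -0.47 (adjusted p = 0.0355, adjusted p = 0.744 with an estimated correlation) and 0.73 and -1.60 within the classes, and the call was lost with the block (median -0.35, adjusted p = 0.0516) and without tumor-free 2, tumor-free 3, fresh 3 or cultured 3 (up to 0.433). It was -0.94, -0.23 and -0.17 without tumor-free 1, 2 and 3. Of 12 hematopoietic progenitor genes 1 fell, the stem cell factor receptor gene Kit, which was also the 1 that fell when adjusted over the list alone and which lost its call when any array other than tumor-free 1 was left out (up to 0.194). Their median was -0.39 (adjusted p = 0.0431, adjusted p = 0.329 with an estimated correlation) and 0.05 and -0.22 within the classes, and the call was lost with the block (median -0.32, adjusted p = 0.11) and without tumor-free 2, tumor-free 3, fresh 2, fresh 3, cultured 1 or cultured 3 (up to 0.106), with a median of -0.26 without cultured 1 and -0.59 without tumor-free 1. None of 4 eosinophil genes passed (2 unadjusted) and 2 fell when adjusted over the list alone, with a median of -0.98 (adjusted p = 0.0387, adjusted p = 0.406 with an estimated correlation), -0.85 with the block and -0.36 and -0.79 within the classes. It was -1.77 without tumor-free 1, -0.62 without tumor-free 3 and -1.48 without cultured 3, and the call was lost without tumor-free 2, tumor-free 3, fresh 3, cultured 1 or cultured 2 (up to 0.125). With the block, the NADPH oxidase list (median 0.59, adjusted p = 0.0166), the plasma cell list (0.60, 0.0195), the cytosolic ribosomal protein list (-0.27, 0.0113) and the stromal and endothelial list (-0.37, 0.0166) passed too. With an estimated correlation and no block, camera's adjusted p for these lists was 0.744, 0.406, 0.757 and 0.744.

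In this comparison 107 probe sets passed limma's test, 51 higher and 56 lower, and 1226 had an unadjusted p below 0.05. The count was 14 in a fit of only the 2 groups compared (5 higher and 9 lower, 1140 unadjusted), 0 with the closest 2 arrays of each group averaged (475 unadjusted), 1389 with array weights (692 and 697) and 204 with the beta-actin covariate (111 and 93). The MHC class II, lysosome, eosinophil and progenitor lists lost their calls in both of the first 2 of these settings, the secondary and tertiary granule list in the first and the cholesterol list in the second. All 80 genes whose representative probe set was called had non-overlapping groups, as did 18.5% of all probe sets tested, against 10% by chance. The count of called probe sets was 529 without tumor-free 1 (265 higher and 264 lower), 27 without tumor-free 2 (12 and 15) and 24 without tumor-free 3 (10 and 14). It was 71 without fresh 2 (36 and 35), 38 without cultured 1 (20 and 18), 39 without cultured 2 (14 and 25) and 222 without cultured 3 (106 and 116). With the spike-in class as a block it was 177, and within the high and low class, with 2 and 1 residual degrees of freedom, 444 and 1725. Since 3 samples against 3 cannot give an exact two-sided p below 0.1, no rank or permutation test was made of single genes.

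**Figure D3:**
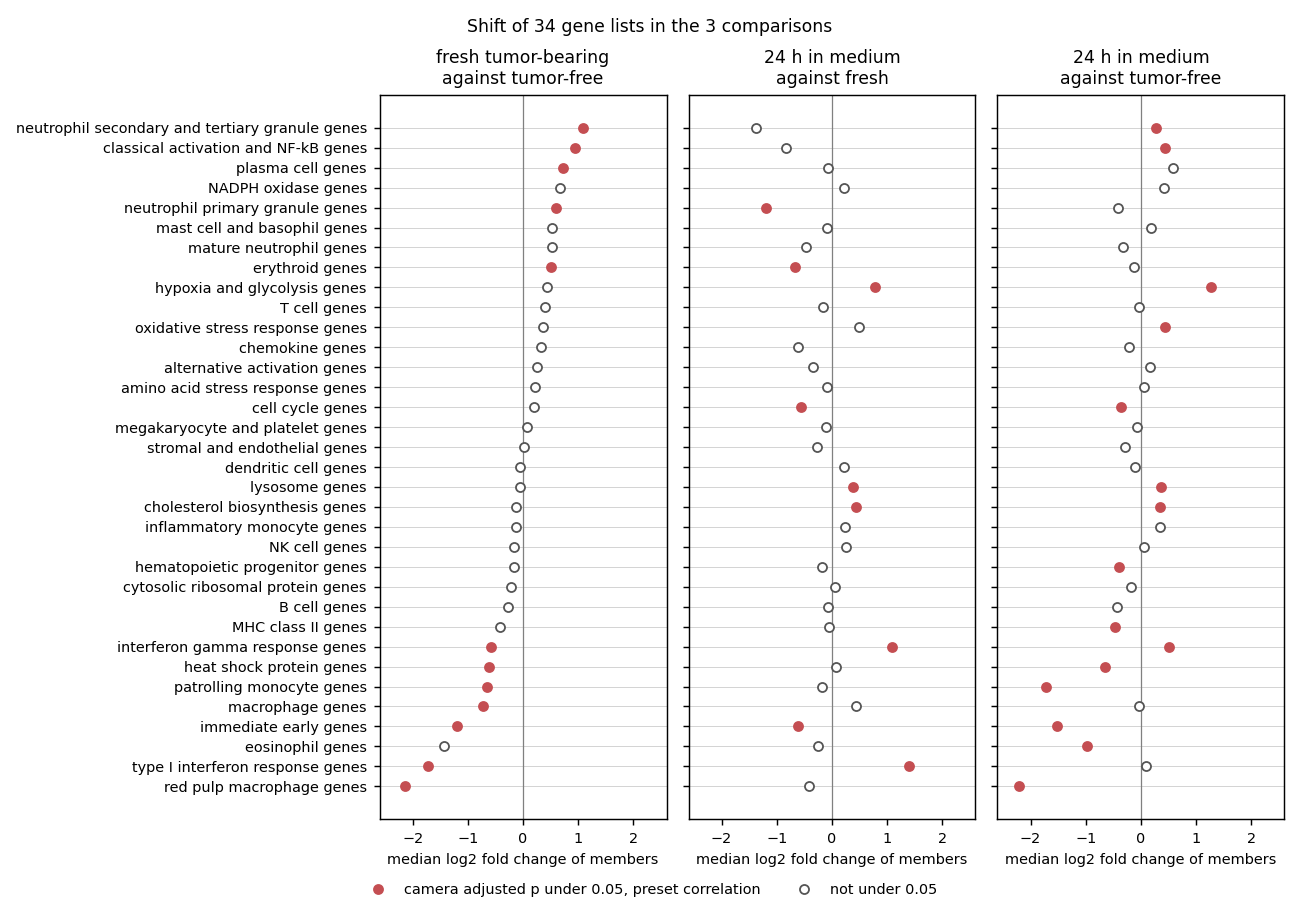
Median log2 fold change of 34 gene lists in the 3 comparisons, 1 point per list, filled where camera's adjusted p with a preset correlation was below 0.05. The type I interferon list lies at -1.73, 1.39 and 0.09 in the first, the second and the third comparison and the immediate early list at -1.20, -0.61 and -1.52.

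Several lists passed camera's test in no comparison as planned, and their medians in the first, the second and the third comparison follow with camera's adjusted p. Mature neutrophil genes had medians of 0.52, -0.47 and -0.32 (0.425, 0.0909 and 0.42), although 2 of 13 fell in the first and the third, Csf3r and the chemokine receptor gene Cxcr2 (-1.72 and -2.28). Cxcr2 lost its call without tumor-free 2 or 3, fresh 1, 2 or 3 or cultured 1 in the first (adjusted p up to 0.17) and without tumor-free 2 or 3 or cultured 1 or 2 in the third (up to 0.0801). Inflammatory monocyte genes had medians of -0.14, 0.23 and 0.35 (0.895, 0.698 and 0.549), the mean in the first being 0.12, opposite in sign. Alternative activation genes had 0.26, -0.34 and 0.16 (0.677, 0.277 and 0.798), the test pointing down in the third. Chemokine genes had 0.32, -0.61 and -0.21 (0.0786, 0.0525 and 0.701), with the second passing, downward, in 11 of 25 alternative settings, among them without tumor-free 1, tumor-free 3, fresh 2 or cultured 3 (0.00534 to 0.553 over all). NADPH oxidase genes had 0.66, 0.22 and 0.41 (0.231, 0.723 and 0.148) and amino acid stress genes 0.22, -0.09 and 0.06 (0.677, 0.894 and 0.726), the second with a mean of 0.12. Cytosolic ribosomal protein genes had -0.23, 0.05 and -0.17 (0.26, 0.894 and 0.144), with the test pointing down in the second. Among marker lists, B cell genes had -0.27, -0.07 and -0.43 (0.396, 0.828 and 0.174), T cell genes 0.40, -0.16 and -0.03 (0.129, 0.651 and 0.539), with the mean 0.15 and the test pointing up in the third, and NK cell genes -0.16, 0.25 and 0.05 (0.907, 0.698 and 0.78). Dendritic cell genes had -0.06, 0.22 and -0.11 (0.899, 0.34 and 0.539), with means of 0.01 and 0.27 in the first and the third, and megakaryocyte and platelet genes 0.08, -0.12 and -0.07 (0.978, 0.621 and 0.539), with a mean of -0.16 in the first. Mast cell and basophil genes had 0.53, -0.10 and 0.18 (0.149, 0.293 and 0.758), and stromal and endothelial genes 0.01, -0.27 and -0.28 (0.907, 0.143 and 0.123), with a mean of -0.09 in the first and the third passing in 7 of 25 alternative settings, among them without tumor-free 2 or 3 (0.00941 to 0.83 over all).

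With an estimated correlation in place of the preset one, camera called 0 of the 34 lists in each comparison, the lowest adjusted p being 0.268, 0.524 and 0.135. At an unadjusted p below 0.05 and the preset correlation 15, 13 and 15 lists passed. The test fry, which asks whether the genes of a list move one way on balance, gave 4 lists in the first comparison, the macrophage, NF-kB, immediate early and plasma cell lists (adjusted p = 0.0408 each), 0 in the second, and in the third the immediate early (0.00859) and oxidative stress (0.0151) lists.

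Of 31 genes chosen for their role in myeloid suppressor function, 27 were measured. In the fresh cells the anti-inflammatory cytokine gene Il10 rose from 8.74 ± 9.43 (SD, n = 3) to 119 ± 16.2 (log2 fold change 3.06 ± 0.53, adjusted p = 0.015), and the granulocyte growth factor receptor gene Csf3r fell from 1304 ± 318 to 510.5 ± 32.2 (-1.31 ± 0.28, adjusted p = 0.0413), while 25 did not pass. 2 rose and 1 fell when adjusted over the list alone. In culture Arg1 rose, Il10 fell to 17.8 ± 20.1 (-2.56 ± 0.53, adjusted p = 0.0272) and 25 did not pass (3 rose and 4 fell when adjusted over the list alone). The array's control probe set for Il10, which was not tested, showed no comparable fall in culture, with signals of 65.8 ± 35.6 in tumor-free, 211 ± 118 in fresh and 191 ± 11.7 in cultured cells. Between cultured and tumor-free cells Arg1 and Cybb rose, Cybb from 191 ± 115 to 944 ± 272 (2.41 ± 0.43, adjusted p = 0.0226), Csf3r fell (-1.79, adjusted p = 0.0133) and 24 did not pass (4 rose and 3 fell when adjusted over the list alone). Itgam, the gene of CD11b itself, had signals of 291 ± 71.5 in tumor-free, 463 ± 106 in fresh and 550.0 ± 350.3 in cultured cells, and the alarmin gene S100a8 13490 ± 2166, 14380 ± 3564 and 11240 ± 4362. Neither differed by the test. The nitric oxide synthase gene Nos2 missed the threshold in the third comparison (1.88, adjusted p = 0.0503). Il10 lost its call in the first comparison without tumor-free 3, fresh 1 or fresh 2 (adjusted p up to 0.0794) and in the second without fresh 1, 2 or 3, cultured 1 or cultured 2 (up to 0.126). Cybb lost its call without tumor-free 3, cultured 1 or cultured 2 (up to 0.086). Csf3r lost it without tumor-free 2 or 3, fresh 1, 2 or 3 or cultured 1 in the first comparison (up to 0.201) and without tumor-free 2 or 3 or cultured 1 or 2 in the third (up to 0.0796).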

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

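The tests of the 3 patterns weighed here were chosen only after the results were seen, whereas the splits of the arrays were planned.

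Control probe sets took no part in the comparisons, and 6 readings among them lay above all 3 tumor-free arrays, by the ratios of mean signal given here; of 56 such comparisons of 28 mouse control probe sets, 2.8 would do so by chance, and as many would lie below all 3. Fresh cells had 3.21 times the tumor-free signal on the Il10 control probe set (211 ± 118 against 65.8 ± 35.6, SD, n = 3) and 5.37 times on the Il2 control probe set (94.0 ± 29.2 against 17.5 ± 9.53). Cultured cells had 2.9 times on the Il10 control probe set (191 ± 11.7), 1.22 times on the antisense beta-actin 5' probe set (86.9 ± 6.22 against 71.4 ± 2.42), 3.55 times on the Gapdh 5' probe set (9895 ± 3833 against 2789 ± 772) and 3.67 times on the Gapdh middle probe set (9873 ± 4172 against 2692 ± 1287). Another 5 readings lay below all 3 tumor-free arrays, namely the 18S ribosomal RNA 3' and 5' probe sets (0.476 and 0.327 times), the 18S middle probe set, at 5.31, 8.57 and 1.19 on the fresh arrays and so too near or below the offset for a ratio, and the antisense beta-actin 5' probe set (0.812 times) in fresh cells, and the beta-actin middle probe set (0.606 times) in cultured cells.

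Pancreas transcripts were higher in the fresh cells than in both other groups. The authors' scaling, which moves all probe sets of an array together, is argued against by the median log2 fold changes. That of the 10 measured digestive enzyme genes was 3.01, and that of all probe sets tested was 0.009. Quantile normalization also gave 3.01 for the enzyme genes, but it could hardly differ, since the arrays already shared a common level. A candidate source is pancreatic acinar RNA or cells carried over when the spleen was removed. The enzyme genes outside the 10 largest rises, which had prompted the list, should then rise too. The median of these 7 was 1.32 and 4 rose. However, the list held 23 enzyme genes, and only the 10 that passed the intensity filter over all arrays, the fresh ones included, were measured. Enzyme genes dim on all arrays could not count against a carry-over, so these values do not decide for it. Pnliprp2 (log2 fold change 1.32), Cela1 (signal 453 against 249) and Pla2g1b (552 against 417), also acinar products, did not pass the test (Prss2 was at a signal of 1635, Ctrb1 at 3920). How far the sort for CD11b removed acinar cells, or RNA bound to sorted cells, was not measured. Expression by the CD11b+ cells of tumor-bearing mice stays open, because the median of -2.21 in culture would follow from either source.

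In each group 1 array stood apart (tumor-free 1, fresh 3, cultured 3). The spike-in level picked the same array as the correlations in 3 of 3 groups, and so did the beta-actin ratio in 3 of 3, a match that chance gives in 1 of 27 placings (0.037), while the Gapdh ratio did so in 2 of 3. These matches ignore direction. On tumor-free 1 both ratios were higher than on its pair (Gapdh 1.63 against 0.924 and 1.11). On fresh 3 the Gapdh ratio was higher (1.69 against 1.07 and 0.993) but the beta-actin ratio lower (1.35 against 1.60 and 1.58). The ratios thus conflict on that array. The spike-in level and the beta-actin ratio need not be separate lines of evidence. A difference in hybridization run or in RNA quality may underlie the pairs. Another cell makeup may contribute too, since the median of the red pulp macrophage list, the largest such difference, was -2.6 for tumor-free 1 minus the other tumor-free arrays (log2), and 4, 1 and 2 of 14 cell type lists differed by over 1 in the tumor-free, fresh and cultured group. None of the 3 explanations excludes the others, and the labels name no further difference within a group.

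Interferon response genes were low in the fresh cells. The mean log2 signal of the type I list was 5.70, 5.48 and 6.05 on the fresh arrays, 7.60, 7.20 and 7.16 on the tumor-free arrays and 6.25, 7.04 and 8.81 on the cultured arrays. With the spike-in class as a block the list median was -1.53 (camera adjusted p = 2.04e-05 with the preset correlation), against -1.73 without it. This argues against that class, as drawn, as the source of most of the shift. The medians within the spike-in classes were below 0 (the higher was -0.767), but each rests on a lone array of 1 group. A run that follows the groups was not tested, so a difference in hybridization run stays open. Chance stays open too, as the 3 fresh arrays held the 3 lowest means of 9 (exact one-sided permutation p = 0.0119, the smallest that 84 placings can give), but this list was picked among 34. A lower interferon response of these cells in tumor-bearing mice also stays open, with an adjusted p of 0.438 when the correlation between genes was estimated.

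With 10 splits of 6 arrays into 3 and 3, the share of splits with as many calls cannot go under 0.05. For fresh against tumor-free cells the real split gave 165 and the highest other 26, so 1 of 10 reached the real value, and for cultured against fresh cells it gave 234 and the others 0 by limma (111 to 929 at an unadjusted p below 0.05), again 1 of 10. For cultured against tumor-free cells the real split gave 107 and another 196, so 2 of 10 did. That split, which exchanges tumor-free 1 and cultured 3, set tumor-free 1, cultured 1 and cultured 2 against the other 3 arrays, as the spike-in class does. The real comparison gave 177 with the class as a block. No other split was run with the block, so this count does not favor the real split.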

How the results depend on the processing

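The spike-in block, the averaging of the closest arrays, the beta-actin covariate and the removal of pancreas probe sets were chosen only after the results were seen; the other settings were planned. Robust variance was not run for gene lists, since camera has no such option. Counts are given for fresh against tumor-free, cultured against fresh and cultured against tumor-free cells, then for opposite calls (165, 234, 107 and 69 as reported). Quantile normalization, centring, the offsets, the floor, the filters, a variance without trend or robust, the minimum fold change and the probe set types kept all of them within 1.5 times. Array weights gave 3174, 1902, 1389 and 980. The spike-in block gave 277, 556, 177 and 135, and the beta-actin ratio as a covariate 402, 441, 204 and 145. With the closest 2 arrays of each group averaged, limma gave 23, 21 and 0 (475 at an unadjusted p below 0.05 in the last) and 16 opposite calls, and 22 of the 60 ranked gene calls were kept, each group then holding 2 samples. A fit of only the 2 groups compared gave 14 for cultured against tumor-free cells. Without the pancreas-related probe sets 31 opposite calls remained, a loss set in part by choosing them by their pattern across these arrays. Apart from the removed probe sets, the cause was not tested. Leaving out 1 array gave 63 to 623, 74 to 489, 24 to 529 and 30 to 188 calls, kept 43 to 60 of the 60 ranked gene calls and gave 27 to 39 called lists against 36. The highest counts of probe sets came without tumor-free 1.

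Of the 60 ranked gene calls, 60 were kept with quantile normalization, the floor, no trend, robust variance, array weights, the spike-in block and the beta-actin covariate, 59 with centring or the offset at the 40th percentile, 58 with no filter, 43 in fits of only the 2 groups, 54 of 54 tested when the lower 50% were left out and 59 of 59 at the 5th percentile. Of the 36 list calls, 36 were kept with quantile normalization, 33 with the spike-in block, 31 with the beta-actin covariate, the averaged arrays or only the 2 groups, 29 with array weights, and 0 by camera with an estimated correlation (15, 13 and 15 lists passed at an unadjusted p below 0.05 with the preset one, and fry called 4, 0 and 2). For cultured against tumor-free cells, 2 lists that had not passed did so in the opposite direction without 1 array. The chemokine median was 0.51 without tumor-free 1 (adjusted p = 0.0435; -0.21 with all arrays; over all settings -0.72 to 0.51, adjusted p 0.0435 to 0.963), and the type I interferon median -0.53 without cultured 3 (adjusted p = 0.0074; 0.09 with all arrays; over all settings -0.53 to 0.87, adjusted p 0.00356 to 0.991). Why these medians reversed was not tested.

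Nothing in the labels says that a replicate number marks a shared mouse or day, and residuals of same-numbered arrays correlated above 0.1 in 5 of 9 pairs only (all 3 pairs of number 1, 2 of number 3 and none of number 2), so the numbers were not taken to pair the samples. Only fresh and cultured arrays could share mice, and their pairs of number 1, 2 and 3 were at 0.17, 0.03 and 0.26. A pairing of these groups alone was not fitted and stays open. Of the 9 arrays, 4 matched their own number best. With the replicate number as a block the counts were 200, 258, 144 and 86, all 60 ranked gene calls were kept, and 38 lists were called, 35 of the 36 among them. Signal over background is unknown without detection calls, and up to 23.6% of an array's values lay below the offset.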

Other observations

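The opposite calls were counted as planned, but the genes below were chosen only after their values were seen.

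Inflammatory and immune genes outside the pancreas lists were also among those that limma called in opposite directions. The neutrophil chemokine gene Cxcl1 was at 3.24 in fresh against tumor-free cells and -3.45 in cultured against fresh cells (log2 fold changes, n = 3 per group), the granulocyte growth factor gene Csf3 at 1.75 and -1.72, and the transcription factor gene Batf at 2.75 and -2.37. In the other direction Mov10, an RNA helicase gene, was at -1.85 and 2.08. Batf kept both calls whichever array was left out (adjusted p up to 0.0162 and 0.0283), but none of these 8 calls held with the closest 2 arrays of each group averaged. Cxcl1 lost its first call without tumor-free 2, tumor-free 3, fresh 1 or fresh 2 (up to 0.0871) and its second without fresh 1, fresh 2 or cultured 2 (up to 0.0582). Csf3 lost the first without tumor-free 2, tumor-free 3, any of the fresh arrays or cultured 2 (up to 0.186) and the second without any of the fresh or cultured arrays (up to 0.144). Mov10 lost the first without tumor-free 2, fresh 1 or fresh 2 (up to 0.133) and the second without fresh 1 or cultured 2 (up to 0.0675).

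Some kallikrein family genes, picked because both comparisons called them, moved as the pancreas genes did, with Klk1b1 at 2.97 and -2.40, Klk1b5 at 2.69 and -3.21 and Klk1b22 at 2.08 and -2.31. Other members of the family were not tallied. Of these 6 calls, only the first of Klk1b5 was lost in a fit without 1 array, namely fresh 1 or fresh 2 (adjusted p up to 0.0554), whereas only the first of Klk1b1 held with the averaged arrays. The family's members are close paralogs, and whether their probe sets tell them apart was not tested.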
